A study of Homo sapiens with 230 samples.

How the data were processed

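Human 585B1 iPSCs, iMeLCs and BMP4-cultured aggregates, or reporter-positive cells sorted from them, were profiled by 3'-end sequencing of amplified cDNA. The deposited table holds all 230 libraries, with 24869 genes and 92 ERCC spike-in RNAs. The authors gave the values as RPM, reads scaled to a common total, and in each library the genes, without the spike-ins, sum to between 1000181.1 and 1000802.5. For part of the columns the deposited sample records name no unit. These are recorded as a signal in RPM by the authors, and they have the same sums and steps as the rest. Per the submitters' processing notes, Trimmomatic 0.35, cutadapt 1.3, TopHat 1.4.1, Cufflinks 2.2.0 and the build hg19 were used, and the notes give no role or order for them. Reads that map to several genes, amplification and the length of the 3' tail covered were fixed before deposition and could not be checked. Replicates were not pooled, and no column of per-sample values was left out.

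Reads on genes per library were recovered from the smallest step between values, which stands for 1 read. They lay between 595898 and 9916798 (median 2672853). Of values of up to 20 reads, between 91.9% and 96.7% were whole reads to within 0.01, so the values were not turned back into counts and no test of counts was run. A value of 0 allows up to 3 reads, and this covers counting error only, since reads without molecular identifiers are not independent molecules. The 2652 genes detected in no library were never tested.

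Each series was fitted apart. RPM values with 1 added were taken to log2 and fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend in the prior variance), with a mean for each genotype and stage. Genes with at least 5 RPM in as many libraries as the smallest group of the series (at least 2) were tested. These were 12695, 12787, 12320, 12640 and 12256 in series 1, 2, 3, 4 and 6, with 54, 52, 30, 28 and 6 residual degrees of freedom. Series 1 had the library code prefix as an additive term, because all EOMES KO libraries and 1 control per stage carried another prefix than the rest. P-values were adjusted by Benjamini and Hochberg within each of 38 comparisons, and a gene was called at an adjusted p under 0.05 and a log2 change of at least 1 in either direction. These p-values measure the spread between libraries, which may be separate cultures or repeats of 1 culture. Clones are nested in genotypes, so a genotype and its clones cannot be separated in full. Library codes of series 1 to 4 run in sets, and libraries of a set deviated from their group means together (median r of 0.370 for SOX17 KO at day 2 and 0.254 for T KO at day 2, -0.136 and -0.0599 between sets). The labels describe neither the deleted part of a gene nor the 3' end of an added one, so reads of a targeted or added gene check neither.

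Before the data were examined, 20 gene lists were fixed: germ cell specification, late germ cell, core pluripotency, naive pluripotency, primed pluripotency, primitive streak, endoderm, somatic mesoderm, amnion and surface ectoderm, HOX, neural, BMP response, WNT response, NODAL response, DNA methylation machinery, cell cycle, p53 response, immediate early and heat shock, endothelial, and fibroblast and smooth muscle. Each was tested in each comparison with limma's camera at the preset correlation of 0.01 and again with an estimated correlation, adjusted over the 20 lists. Counts of called members are given over all genes and adjusted over the list alone. The rule for named genes, also fixed before, took the 6 targeted or added genes in every comparison and up to 4 members of a list by the size of their log2 change. It also took the 6 largest changes in each direction (3 in iPSCs and iMeLCs) among called genes with a mean of at least 20 RPM in the higher group and no overlap between the libraries of the groups. Genes outside the rule are named as such. Some genes that met it are not reported here.

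The design was tested on simulated data with 200 changed genes in 8 comparisons. At a log2 change of 1.5, between 67.2% (BLIMP1 KO, day 4) and 92.5% (SOX17 KO, day 2) of the changed genes were recovered. At a log2 change of 2 this was between 82.1% and 100%, and between 1 and 9 unchanged genes were called. Differences of a KO effect between stages were tested as limma contrasts for the targeted gene and list members. Stage identity was checked in 224 libraries (series 5 has no groups) by correlating each with all groups of its series over 2000 variable genes. Other splits of the libraries into groups of the same sizes, at most 100, were refitted for the 27 comparisons with at least 3 libraries a group. Spread within groups of 4 to 10 libraries was tested with Dixon's ratio on the mean of the germ cell specification and primitive streak lists.

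Alternatives fixed beforehand were a pseudocount of 4, no filter (genes above 0 in at least 1 library), scaling of each library by its median ratio to the geometric mean, a fit of only the 2 groups compared, and 1 value per clone. Others were the prefix term left out (series 1) or put in (series 2), only libraries of prefix MS102 (series 1), the same step in controls of other series, and leaving out each library in turn. Leaving out 4 doubtful libraries of series 3 was added after the data were seen. Spike-ins were present in 128 libraries and absent from 102, and were not used for scaling. Series 5 has 1 library per stage and gives values without a test. Data were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9.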

Results

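RNA was sequenced from 230 libraries of human cells taken along an in vitro course to germ cell fate. The cells were 585B1 human induced pluripotent stem cells (iPSCs, an established line) and incipient mesoderm-like cells (iMeLCs) made from them with Activin A and the WNT agonist CHIR99021. From these came aggregates cultured with BMP4, in which primordial germ cell-like cells (PGCLCs) arise. The libraries fall into 6 series. Series 1 holds unsorted iPSCs, iMeLCs, day 1 and day 2 aggregates with 5 control, 8 SOX17 knock-out (KO) and 4 EOMES KO libraries per stage. Series 2 holds iPSCs, iMeLCs and cells sorted at days 2 and 4 on a BLIMP1-tdTomato reporter (BT), with 5 control, 5 TFAP2C KO and 6 T KO libraries per stage. Series 3 holds iPSCs, iMeLCs, unsorted day 1 aggregates and cells sorted at days 2 and 4 on BT and a TFAP2C-EGFP reporter (BTAG), with 4 control and 4 MIXL1 KO libraries, of a single clone, per stage. In series 4 (2 control libraries per stage) EOMES KO cells carried an added EOMES or an added SOX17 (4 libraries of each per stage), again as iPSCs, iMeLCs and BTAG-sorted cells at days 2 and 4. Series 5 is a single control course to day 8, without replicates. Series 6 holds 2 control and 2 BLIMP1 KO libraries each of iPSCs and of BTAG-sorted cells at days 2 and 4. BLIMP1 is the protein made by PRDM1.

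Each library gave between 595898 and 9916798 reads on genes (median 2672853), recovered from the smallest step between values. A single read stood for between 0.101 and 1.68 RPM (reads scaled to a common total per library). Libraries of 1 group correlated across genes with Pearson's r of at least 0.919 (median 0.979, 434 pairs of libraries, over all genes, which are not independent replicates). Of the 6 genes that were knocked out or added, 3 are SOX17 (Entrez 64321, chromosome 8, 54457935 to 54460888), EOMES (Entrez 8320, chromosome 3, 27715949 to 27722711) and TFAP2C (Entrez 7022, chromosome 20, 56629302 to 56639283). The others are T (brachyury, named TBXT in the annotation, Entrez 6862, chromosome 6, 166157656 to 166168700), MIXL1 (Entrez 83881, chromosome 1, 226223618 to 226227054) and PRDM1 (Entrez 639, chromosome 6, 106086320 to 106109939). These positions are protein-coding genes of GENCODE release 29 on GRCh38, whereas the deposited values rest on the hg19 build. Values below are mean RPM ± SD with the knock-out or later stage first, and log2 changes carry ± SE where given.

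The control course of series 3 asked which transcripts mark each step. From iPSCs to iMeLCs, the NODAL antagonists CER1 (809 ± 679 against 0.955 ± 1.54 RPM, log2 change 8.48 ± 1.04, adjusted p = 5.81e-07, n = 4 and 4) and LEFTY2 (643 ± 331 against 5.14 ± 8.34 RPM, log2 change 7.38) rose. The T-box factor EOMES rose to 193 ± 85.3 RPM (log2 change 6.55). T (67 ± 29.4 against 0.737 ± 0.586 RPM, log2 change 5.25) and the homeobox gene MIXL1 (369 ± 233 against 2.42 ± 0.722 RPM, log2 change 6.55) rose too. NPTX1, a neuronal pentraxin (0.124 ± 0.247 against 125 ± 31.8 RPM, log2 change -6.79), and SFRP1, a secreted WNT inhibitor (87.7 ± 26.9 against 1168 ± 153 RPM, log2 change -3.75), fell. Among the fixed lists, the primitive streak genes had 10 of 15 tested members higher (10 higher adjusted over the list alone), with a median log2 change of 3.81. For primitive streak genes camera gave adjusted p = 8.75e-20, and adjusted p = 0.00237 with an estimated correlation. The NODAL response genes had 7 of 10 tested members higher (7 higher adjusted over the list alone), with a median log2 change of 5.22. For NODAL response genes camera gave adjusted p = 2.13e-17, and adjusted p = 6.58e-06 with an estimated correlation. WNT response genes, among them the WNT antagonist DKK4 (103 ± 102 against 0.0504 ± 0.101 RPM), had 5 of 14 tested members higher (5 higher adjusted over the list alone), with a median log2 change of 0.98. For WNT response genes camera gave adjusted p = 1.35e-08, and adjusted p = 0.00571 with an estimated correlation. The fibroblast and smooth muscle list moved through the cytoskeletal genes VIM (3005 ± 180.4 against 266 ± 43.1 RPM) and TAGLN (514 ± 115 against 66.2 ± 19.1 RPM). It had 5 of 12 tested members higher (5 higher adjusted over the list alone), with a median log2 change of 1.11. For fibroblast and smooth muscle genes camera gave adjusted p = 1.92e-07, and adjusted p = 0.00837 with an estimated correlation. In all 344 genes rose and 247 fell (limma). The count was 920 without 4 doubtful libraries of other stages and 893 when iPSCs and iMeLCs alone entered the fit.

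From iMeLCs to day 1 the BMP response genes had 11 of 12 tested members higher (11 higher adjusted over the list alone), with a median log2 change of 3.86. For BMP response genes camera gave adjusted p = 4.62e-20, and adjusted p = 0.000333 with an estimated correlation. Its member GATA3, a factor of trophectoderm and amnion, went to 209 ± 116 against 1.2 ± 1.92 RPM, log2 change 6.61. TFAP2A went to 73.2 ± 35.6 RPM from libraries at 0. HAND1, a mesoderm and amnion factor (1292 ± 1286 against 0.434 ± 0.504 RPM, log2 change 9.16 ± 1.06, adjusted p = 7.34e-08, n = 4 and 4), rose. So did the T-box factor TBX3 (153 ± 93.1 against 0.333 ± 0.391 RPM, log2 change 6.64). The somatic mesoderm list had 13 of 15 tested members higher (15 higher adjusted over the list alone), with a median log2 change of 4.20. For somatic mesoderm genes camera gave adjusted p = 4.76e-13, and adjusted p = 0.0238 with an estimated correlation. Amnion and surface ectoderm genes had 8 of 12 tested members higher (11 higher adjusted over the list alone), with a median log2 change of 4.09. For amnion and surface ectoderm genes camera gave adjusted p = 1.08e-11, and adjusted p = 0.0021 with an estimated correlation. NODAL targets fell again, LEFTY1 to 3.9 ± 6.24 against 736 ± 240.5 RPM and NODAL itself to 11.3 ± 7.25 against 383 ± 72.7 RPM. So did SOX2, a pluripotency factor (3.12 ± 4.17 against 190.1 ± 48.6 RPM, log2 change -6.01). The NODAL response list had 7 of 10 tested members lower (7 lower adjusted over the list alone), with a median log2 change of -4.40. Tested by camera, NODAL response genes had adjusted p = 3.24e-09, and adjusted p = 0.000774 with an estimated correlation. The primed pluripotency list had 8 of 13 tested members lower (10 lower adjusted over the list alone), with a median log2 change of -1.56. For primed pluripotency genes camera gave adjusted p = 2.47e-09, and adjusted p = 0.00736 with an estimated correlation. Of the germ cell regulators, SOX17 (178 ± 126 against 16.3 ± 12.2 RPM, log2 change 3.45) and TFAP2C (173 ± 144 against 11.2 ± 4.76 RPM, log2 change 3.59) rose. PRDM1 rose with them (76.7 ± 80 against 7.7 ± 2.36 RPM, log2 change 2.66). Without the doubtful control day 1 replicate 4 the day 1 means were 37.4 ± 18 RPM for PRDM1 and 102 ± 35 RPM for TFAP2C, and both still passed. Germ cell specification genes, which lost their call with the other correlation, had 6 of 15 tested members higher and 1 lower (6 higher and 1 lower adjusted over the list alone), with a median log2 change of 1.13. For germ cell specification genes camera gave adjusted p = 0.00978, and adjusted p = 0.483 with an estimated correlation. Without the doubtful libraries its median was 0.42 and the adjusted p = 0.0635. HOX genes had 6 of 9 tested members higher (7 higher adjusted over the list alone), with a median log2 change of 3.21. For HOX genes camera gave adjusted p = 0.000209, and adjusted p = 0.0692 with an estimated correlation. Without the doubtful libraries this was adjusted p = 0.00358 with an estimated correlation. The short late germ cell list had 2 of 3 tested members lower (2 lower adjusted over the list alone), with a median log2 change of -1.43. For late germ cell genes camera gave adjusted p = 0.00452, and adjusted p = 0.0461 with an estimated correlation. Without the doubtful libraries this was adjusted p = 0.0744 with an estimated correlation. Its meiotic gene TEX15 stood at 0.581 ± 0.435 against 11.4 ± 2.92 RPM. In all 973 genes rose and 489 fell (limma).

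The steps from day 1 on include libraries among the 4 of series 3 that resembled another stage than labelled. These are labelled control day 1 replicate 4, control day 2 replicate 1, control day 4 replicate 2 and MIXL1 KO day 1 replicate 2. Day 1 aggregates were unsorted and cells of days 2 and 4 were BTAG-sorted. From day 1 to day 2 time and sort therefore cannot be told apart. With all libraries, 100 genes passed from day 1 to day 2 (61 higher, 39 lower, limma). From day 2 to day 4 the number was 122 (27 higher, 95 lower). Without the 4 libraries, an alternative chosen after the values were seen, the counts were 2303 and 970. In that fit NANOG, a pluripotency factor of germ cells, rose from day 1 to day 2 (888 ± 105 against 37.8 ± 16.5 RPM, log2 change 4.63 ± 0.28, adjusted p = 2.58e-15, n = 3 and 3). The same held for SOX17 (578 ± 139 against 118 ± 43.1 RPM, log2 change 2.33) and IGF1, a growth factor (1092 ± 156 against 8.92 ± 8.47 RPM, log2 change 7.20). The germ cell specification list then had 15 of 15 tested members higher, with a median log2 change of 2.92. Tested by camera, germ cell specification genes had adjusted p = 2.29e-17, and adjusted p = 2.65e-05 with an estimated correlation. From day 2 to day 4, TCL1A, an AKT co-activator expressed in germ cells, rose (340.1 ± 111 against 39.2 ± 27.4 RPM, log2 change 3.26). So did NANOS3, an RNA-binding protein that germ cells need to survive (153 ± 11.9 against 33.1 ± 13.2 RPM, log2 change 2.25). As a list the germ cell specification genes did not pass at this step (5 of 15 tested members higher and 1 lower, adjusted p = 0.274). With all libraries the genes of largest change were other ones. At day 2 ERMN (50.5 ± 39.7 against 4.11 ± 3.62 RPM, log2 change 3.23) and IGFBPL1 (151 ± 59.7 against 28.9 ± 7.85 RPM, log2 change 2.28) were higher. RSPO3, a WNT potentiator, was lower (3.01 ± 4.69 against 38.5 ± 24.1 RPM, log2 change -3.68). At day 4 STAT5B, a factor of cytokine signalling (31.5 ± 6.98 against 11.9 ± 4.32 RPM, log2 change 1.38), was higher and the glypican GPC4 (16.4 ± 21.7 against 131 ± 25.2 RPM, log2 change -3.62) lower. When the 2 groups compared entered the fit alone, 0 genes passed at either step (1264 and 914 at an unadjusted p under 0.05, limma). Leaving out single libraries gave 20 (control day 2 replicate 2) to 1010 genes (control day 2 replicate 1) at the first step. At the second it gave 30 (control day 2 replicate 2) to 630 (control day 4 replicate 2).

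In the unsorted aggregates of series 1, a lower level per cell and fewer germ cells cannot be told apart. The SOX17 KO comparisons asked which transcripts changed in the KO of SOX17, a SRY-box factor of endoderm and germ cells. Its own reads were near the floor in iPSCs (0.171 ± 0.484 against 0.233 ± 0.323 RPM) and did not pass in iMeLCs (8.92 ± 12 against 2.59 ± 4.12 RPM). At day 1 they were 58 ± 37.3 against 102 ± 84.3 RPM (log2 change -0.33, adjusted p = 0.996). At day 2 they were 0.694 ± 1.46 against 125 ± 68.5 RPM, log2 change -6.07 ± 0.56, adjusted p = 1.84e-13 (n = 8 and 5). NANOG fell to 0.907 ± 1.54 against 135 ± 70.4 RPM, log2 change -6.23 ± 0.22, adjusted p = 6.95e-34. PRDM1 fell to 0.41 ± 0.461 against 55.9 ± 35.5 RPM, log2 change -5.06 ± 0.38, adjusted p = 5.54e-17. TFAP2C (38.7 ± 18.4 against 176 ± 95.2 RPM, log2 change -2.33) and T (9.53 ± 6.02 against 37.4 ± 14.4 RPM, log2 change -1.90) fell less far. The pluripotency factor POU5F1 fell too (427 ± 106 against 887 ± 294 RPM, log2 change -1.13). EOMES (1.04 ± 1.03 against 0.857 ± 0.79 RPM) and MIXL1 (2.35 ± 3.82 against 4.94 ± 4.01 RPM) did not pass. The germ cell specification list had 10 of 12 tested members lower (10 lower adjusted over the list alone), with a median log2 change of -2.33. Camera placed germ cell specification genes at adjusted p = 7.73e-39, and at adjusted p = 5.2e-12 with an estimated correlation. Its examples include LAMA4, a laminin chain (1.6 ± 1.06 against 51.3 ± 29.4 RPM), and PDPN, podoplanin (79.6 ± 12.9 against 999 ± 458 RPM). The core pluripotency list had 3 of 11 tested members lower (3 lower adjusted over the list alone), with a median log2 change of -0.26. For core pluripotency genes camera gave adjusted p = 0.000112, and adjusted p = 0.0218 with an estimated correlation. Its called members were NANOG, POU5F1 and the NODAL co-receptor TDGF1 (7.51 ± 7.45 against 18.7 ± 11.9 RPM). Outside the lists SOSTDC1, a BMP and WNT antagonist (0.128 ± 0.242 against 41 ± 24.4 RPM, log2 change -4.86), fell. The kinase PIM2 (2.98 ± 1.84 against 119 ± 63.4 RPM, log2 change -4.74) and IGF1 (3.34 ± 1.24 against 110.1 ± 44.8 RPM, log2 change -4.58) fell with it.

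Further lists passed in these day 2 aggregates with the preset correlation and not with the estimated one. NODAL response genes had 3 of 10 tested members lower (3 lower adjusted over the list alone), with a median log2 change of -0.24. Camera placed NODAL response genes at adjusted p = 0.0437, and at adjusted p = 0.363 with an estimated correlation. LEFTY1 (0.283 ± 0.334 against 5.98 ± 3.09 RPM) and LEFTY2 (6.02 ± 5.63 against 27.1 ± 13.7 RPM) fell. Amnion and surface ectoderm genes had 0 of 13 tested members called (0 adjusted over the list alone), with a median log2 change of 0.40. Tested by camera, amnion and surface ectoderm genes had adjusted p = 0.0437, and adjusted p = 0.586 with an estimated correlation. In all 21 genes were higher and 299 lower of 320 called (limma), and none of the 21 met the rule for naming. At day 1, 4 genes passed, named after their values were seen. COL23A1 (2.56 ± 1.98 against 13.6 ± 6.43 RPM, log2 change -1.95) and GJA4 (0.867 ± 0.509 against 7.43 ± 5.96 RPM, log2 change -1.78) were lower. VSTM2B (0.337 ± 0.443 against 2.33 ± 0.512 RPM, log2 change -1.37) was lower and FAM131B (10.5 ± 2.03 against 3.96 ± 1.64 RPM, log2 change 1.20) higher. No gene passed in iPSCs (0, with 346 at an unadjusted p under 0.05 in limma) or iMeLCs (0, with 353), where late germ cell genes had 0 of 3 tested members called (0 adjusted over the list alone), with a median log2 change of 0.81. Tested by camera, late germ cell genes had adjusted p = 0.00341, and adjusted p = 0.0354 with an estimated correlation. The day 2 count was 172 with 1 value per clone, 158 when the 2 groups alone entered the fit and 175 with a pseudocount of 4. The day 1 count lay between 1 and 10 when single libraries were left out, and was 2 with sets of neighbouring library codes as a paired block. With that block the day 2 amnion and surface ectoderm genes had adjusted p = 0.208.

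**Figure D1:**
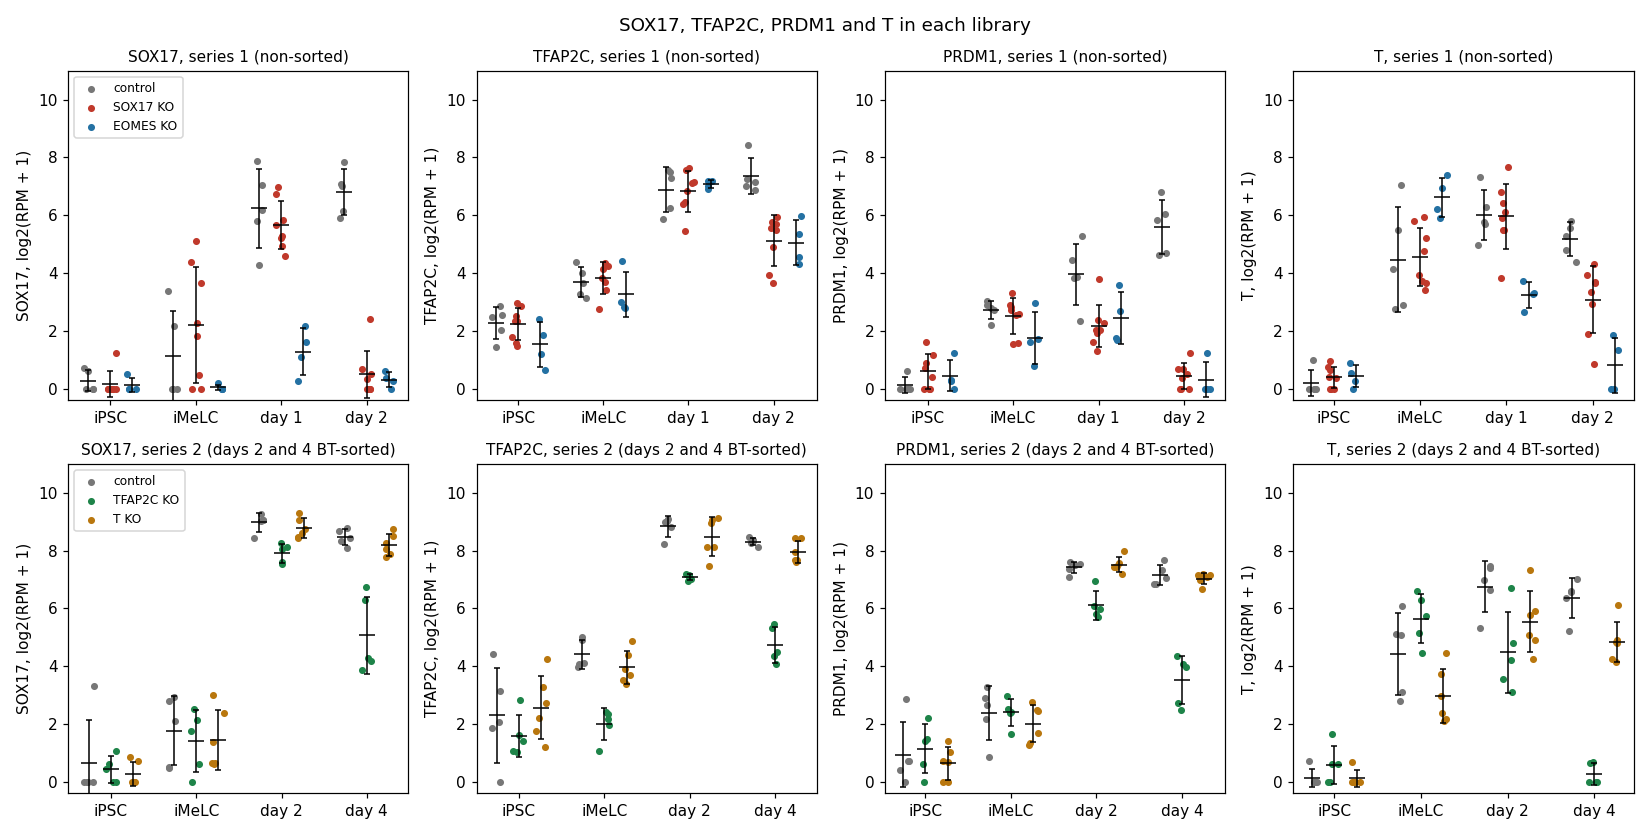
SOX17, TFAP2C, PRDM1 and T in series 1 and 2, as log2(RPM + 1) on the vertical axis, by genotype and stage on the horizontal axis; points are libraries and bars mean ± SD. PRDM1 in SOX17 KO aggregates at day 2 averaged 0.41 RPM and in EOMES KO aggregates 0.335 RPM, against 55.9 RPM in controls.

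The EOMES KO comparisons asked the same of EOMES, with the same limit for unsorted aggregates. EOMES reads were 0.191 ± 0.224 against 0.065 ± 0.145 RPM in iPSCs and 78.2 ± 26.2 against 89.7 ± 95.5 RPM in iMeLCs. They were 6.42 ± 2.07 against 49.8 ± 20.9 RPM, log2 change -3.45 ± 0.54, adjusted p = 2.99e-05 at day 1 (n = 4 and 5) and 0.196 ± 0.278 against 0.857 ± 0.79 RPM at day 2. The labels do not say which part of the gene was removed. In iMeLCs, 27 genes passed (8 higher, 19 lower). With MS102 libraries alone, which hold a single control per stage, 1 was higher and 25 lower. The caudal factor CDX1 (27.1 ± 16.9 against 2.42 ± 2.63 RPM, log2 change 3.47 ± 0.55, adjusted p = 0.000201) rose. So did the homeobox gene GBX2 (48.8 ± 11.7 against 8.65 ± 6.52 RPM, log2 change 2.42). The tight junction gene CLDN11 fell (2.02 ± 0.737 against 28.2 ± 12.8 RPM, log2 change -3.96). The retinoic acid-degrading enzyme CYP26A1 (5.81 ± 2.43 against 66.6 ± 30.1 RPM, log2 change -3.83) and the anterior factor OTX2 (5 ± 3.02 against 28.8 ± 5.77 RPM, log2 change -2.96) fell. At day 1 SOX17 fell to 1.72 ± 1.41 against 102 ± 84.3 RPM, log2 change -5.92 ± 0.78, adjusted p = 6.53e-07. MIXL1 fell to 2.56 ± 2.04 against 44.2 ± 44.2 RPM, log2 change -4.59. T (8.74 ± 2.82 against 74.1 ± 50 RPM, log2 change -3.54) and PRDM1 (5.26 ± 4.14 against 17.8 ± 12.5 RPM, log2 change -1.94) fell as well. TFAP2C stood at 134 ± 12.5 against 131 ± 60.7 RPM and did not pass. The neuropeptide gene GAL (52.4 ± 7.12 against 476 ± 192 RPM, log2 change -3.40) fell, and IGFBP3, an IGF-binding protein (77.8 ± 5.01 against 20.9 ± 12.8 RPM, log2 change 3.59), rose. The retinoic acid-synthesising enzyme ALDH1A2 (34.7 ± 7.2 against 4.95 ± 3.87 RPM, log2 change 3.16) and the chemokine CXCL12 (884 ± 82.2 against 205 ± 139 RPM, log2 change 2.97) rose.

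By list, the primitive streak genes of the day 1 aggregates had 9 of 16 tested members lower (12 lower adjusted over the list alone), with a median log2 change of -2.10. Their camera adjusted p was 6.32e-14, and 0.00829 with an estimated correlation. The amnion and surface ectoderm list had 5 of 13 tested members higher (9 higher adjusted over the list alone), with a median log2 change of 1.28. Its camera adjusted p was 5.48e-11, and 0.00829 with an estimated correlation. Neural genes had 2 of 9 tested members higher (4 higher adjusted over the list alone), with a median log2 change of 0.78. Camera gave adjusted p = 0.0024, and 0.0478 with an estimated correlation. Endoderm genes had 1 of 8 tested members higher and 3 lower (1 higher and 5 lower adjusted over the list alone), with a median log2 change of -2.02. Their camera adjusted p was 0.0024, and 0.0964 with an estimated correlation. In all 190 genes were higher and 158 lower. At day 2, SOX17 (0.257 ± 0.225 against 125 ± 68.5 RPM, log2 change -7.46) and NANOG (0.17 ± 0.2 against 135 ± 70.4 RPM, log2 change -6.79 ± 0.31, adjusted p = 9.82e-28) had fallen. PRDM1 (0.335 ± 0.669 against 55.9 ± 35.5 RPM, log2 change -5.71) and T (1.05 ± 1.3 against 37.4 ± 14.4 RPM, log2 change -5.14) were almost absent. TFAP2C (35.9 ± 19.9 against 176 ± 95.2 RPM, log2 change -1.91) and the WNT ligand WNT2 (1.53 ± 0.915 against 68.9 ± 39.2 RPM, log2 change -5.15) were lower too. The germ cell specification list had 9 of 12 tested members lower (9 lower adjusted over the list alone), with a median log2 change of -1.96. Its camera adjusted p was 5.01e-17, and 1.02e-06 with an estimated correlation. Core pluripotency genes had 3 of 11 tested members lower (4 lower adjusted over the list alone), with a median log2 change of -0.57. Tested by camera, core pluripotency genes had adjusted p = 7.6e-05, and adjusted p = 0.0152 with an estimated correlation. NODAL response genes had 4 of 10 tested members lower (6 lower adjusted over the list alone), with a median log2 change of -1.67. For NODAL response genes camera gave adjusted p = 2.99e-05, and adjusted p = 0.0119 with an estimated correlation. In the other direction, amnion and surface ectoderm genes had 5 of 13 tested members higher (7 higher and 1 lower adjusted over the list alone), with a median log2 change of 1.01. For amnion and surface ectoderm genes camera gave adjusted p = 7.01e-07, and adjusted p = 0.0334 with an estimated correlation. The neural list had 3 of 9 tested members higher (3 higher adjusted over the list alone), with a median log2 change of 1.03. Tested by camera, neural genes had adjusted p = 4.26e-05, and adjusted p = 0.00721 with an estimated correlation. Primitive streak genes had 7 of 16 tested members lower (1 higher and 9 lower adjusted over the list alone), with a median log2 change of -1.33. Camera placed primitive streak genes at adjusted p = 7.01e-07, and at adjusted p = 0.0659 with an estimated correlation.

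At day 2, 208 genes were higher and 544 lower in EOMES KO aggregates (limma). The median gene lay at -0.11. Rescaling each library moved it by 0.104 and the share called higher from 27.7% to 38.0% (287 higher and 468 lower). No gene passed in EOMES KO iPSCs (0, with 821 at an unadjusted p under 0.05 in limma). Without control replicate 5, the sole control that shared its library code prefix with the EOMES KO, the counts were 103 at day 1 and 262 at day 2. With the 2 groups alone in the fit they were 1 in iMeLCs, 165 at day 1 and 11 at day 2. Without the prefix as a term they were 56 in iMeLCs and 187 at day 1. Leaving out EOMES KO replicate 2 or 3 in iMeLCs gave 16 or 13.

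SOX17 KO and EOMES KO shared genes at day 2. In number 208 were lower in both, against 12.8 for unrelated lists of these sizes, and 0 moved in opposite directions. The comparisons use the same controls, which by itself ties their changes. With the controls divided between them 147 genes were lower in both (13.0 for unrelated lists), 6 moved in opposite directions, and r was 0.234. With the library code prefixes kept apart 157 were lower in both (12.5), 1 moved in opposite directions and r was 0.413, but the EOMES KO then had 1 control. In 20 simulated data sets with no change the changes had a median r of 0.407 and covariance of 0.0301, against 0.604 and 0.168 observed.

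The TFAP2C KO comparisons concerned TFAP2C, the AP-2 gamma factor of germ cells, amnion and trophoblast. Its reads were 2.39 ± 2.1 against 6.82 ± 8.12 RPM in iPSCs and 3.21 ± 1.3 against 21.3 ± 7.86 RPM, log2 change -2.41 ± 0.43, adjusted p = 0.00708 in iMeLCs (n = 5 and 5). In sorted cells they were 135 ± 9.95 against 468 ± 100.3 RPM, log2 change -1.76 at day 2. At day 4 they were 27.7 ± 12.4 against 317 ± 26.9 RPM, log2 change -3.57 ± 0.43, adjusted p = 2.77e-10. These cells were sorted on the BLIMP1 reporter, although PRDM1 was lower in them (71.7 ± 29.7 against 172 ± 22.8 RPM at day 2). At day 4 PRDM1 was at 12.1 ± 6.51 against 144 ± 37.6 RPM, log2 change -3.62 ± 0.38, adjusted p = 4.9e-12. At day 2 NANOG fell (70.4 ± 28.4 against 551 ± 99.5 RPM, log2 change -3.02 ± 0.29, adjusted p = 3.08e-12). POU5F1 (955 ± 149 against 2565 ± 672 RPM, log2 change -1.40) and T (33.3 ± 39.6 against 121 ± 55.6 RPM, log2 change -2.27) also fell, and SOX17 (245 ± 54.1 against 512 ± 99.2 RPM) did not pass. ENPP2, the enzyme autotaxin (158 ± 74 against 18 ± 8.21 RPM, log2 change 3.03), and GREM1, a BMP antagonist (141 ± 50.1 against 16.7 ± 5.82 RPM, log2 change 3.03), rose. The germ cell specification list had 11 of 15 tested members lower (13 lower adjusted over the list alone), with a median log2 change of -1.76. Its camera adjusted p was 1.69e-13, and 0.000238 with an estimated correlation. The naive-state factor TFCP2L1 fell (1.84 ± 1.39 against 35.7 ± 11 RPM, log2 change -3.78). HOX genes had 8 of 14 tested members higher (9 higher adjusted over the list alone), with a median log2 change of 1.28. Their camera adjusted p was 8.19e-06, and 0.134 with an estimated correlation.

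At day 4 the germ cell genes were far lower in TFAP2C KO cells. TCL1A was at 2.8 ± 2.71 against 335 ± 51.5 RPM, log2 change -6.84 ± 0.66, adjusted p = 2.21e-13. NANOS3 (3.4 ± 1.33 against 247 ± 84.4 RPM, log2 change -5.80) and T (0.24 ± 0.329 against 87.6 ± 33.6 RPM, log2 change -6.09) fell. NANOG (10.2 ± 6.29 against 629 ± 82 RPM, log2 change -5.96) and SOX17 (46.4 ± 42.4 against 358 ± 69.2 RPM, log2 change -3.39) were lower at this stage. The germ cell specification list had 15 of 15 tested members lower (15 lower adjusted over the list alone), with a median log2 change of -3.57. Camera gave adjusted p = 2.87e-17, and 2.43e-05 with an estimated correlation. Core pluripotency genes had 8 of 12 tested members lower (8 lower adjusted over the list alone), with a median log2 change of -1.50. Their camera adjusted p was 4.56e-06, and 0.0104 with an estimated correlation. Amnion and surface ectoderm genes instead had 13 of 13 tested members higher (13 higher adjusted over the list alone), with a median log2 change of 3.90. Their camera adjusted p was 7.91e-11, and 0.0104 with an estimated correlation. Examples are VTCN1, a B7 family protein (227 ± 57.3 against 5.99 ± 3.01 RPM, log2 change 5.09 ± 0.56, adjusted p = 1.79e-11), and HAND1 (1705 ± 413 against 72.1 ± 35.6 RPM). The somatic mesoderm list, which shares HAND1 and ISL1 with the former, had 12 of 14 tested members higher (12 higher adjusted over the list alone), with a median log2 change of 3.59. Tested by camera, somatic mesoderm genes had adjusted p = 2.4e-08, and adjusted p = 0.0104 with an estimated correlation. HOX genes had 13 of 14 tested members higher and 1 lower (13 higher and 1 lower adjusted over the list alone), with a median log2 change of 3.73. Camera gave adjusted p = 6.66e-10, and 0.0104 with an estimated correlation. Outside the lists, the gastrin receptor gene CCKBR (213 ± 92.9 against 3.77 ± 2.83 RPM, log2 change 5.72) and IGFBP5 (118 ± 61.9 against 1.64 ± 1.06 RPM, log2 change 5.51) rose. The transporter gene ABCG2 rose too (246 ± 90.8 against 7.36 ± 2.26 RPM, log2 change 4.85). The channel gene TRPC6 (0.814 ± 0.954 against 120.4 ± 8 RPM, log2 change -6.22) and the lectin-like receptor KLRB1 (0.956 ± 1.27 against 118 ± 12.5 RPM, log2 change -6.14) fell.

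Markers of other cell types moved with this group. Endothelial genes stood high in replicates 1 and 4, of neighbouring library codes, with KDR at 446 and 356 RPM. These libraries also carried the SOX17 mean, at 106 and 76.9 RPM against 17.2, 13.6 and 18.7 RPM in the others. The fibroblast and smooth muscle list had 9 of 12 tested members higher and 1 lower (9 higher and 1 lower adjusted over the list alone), with a median log2 change of 2.04. Tested by camera, fibroblast and smooth muscle genes had adjusted p = 0.00157, and adjusted p = 0.0986 with an estimated correlation. The proteoglycan LUM was at 677 ± 149 against 69.2 ± 52.1 RPM and COL3A1 at 976 ± 319.7 against 123 ± 97.2 RPM. In all 570 genes were higher and 538 lower at day 2, and 1905 and 1311 at day 4 (limma). In iMeLCs 4 genes passed, TFAP2C, PRODH, a proline dehydrogenase (36.2 ± 12.6 against 105 ± 42.3 RPM, log2 change -1.52), TMEM64 (43.7 ± 17.7 against 103 ± 7.76 RPM, log2 change -1.32) and FAM20A. FAM20A was named after its value was seen (1.86 ± 0.878 against 10.8 ± 6.5 RPM, log2 change -1.91). In iPSCs 1 gene passed, the semaphorin SEMA4A, likewise named afterwards (2.73 ± 1.99 against 8.24 ± 1.53 RPM, log2 change -1.53). The iMeLC count lay between 0 and 4 and the iPSC count between 0 and 11 as single libraries were left out. A pseudocount of 4 gave 656 genes at day 2.

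**Figure D2:**
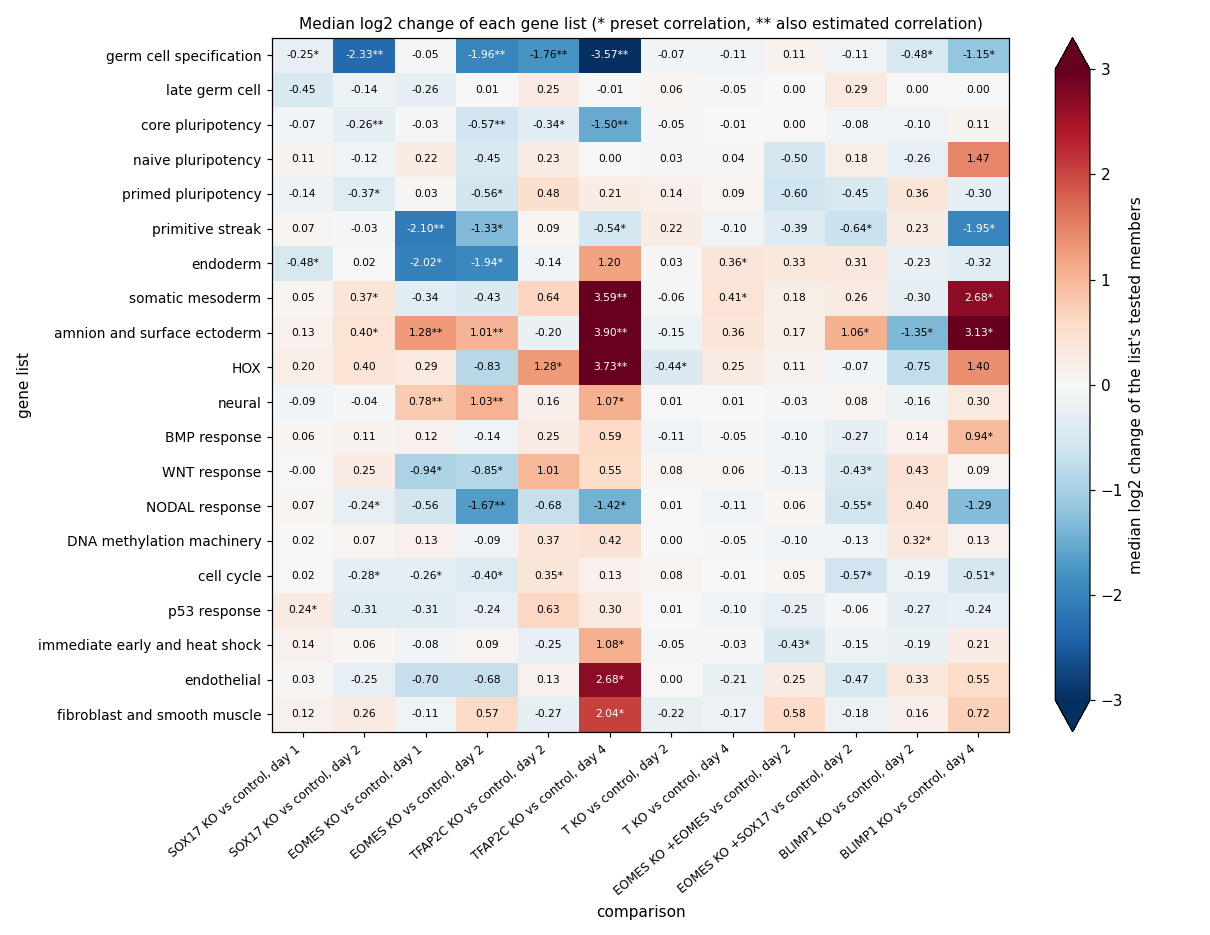
Median log2 change (colour, clipped at 3 in either direction, with the value printed) of the 20 gene lists (vertical axis) in 12 comparisons (horizontal axis). A star marks a camera adjusted p under 0.05 with the preset correlation and a pair of stars one that also passed with the estimated correlation, as for the germ cell specification list in TFAP2C KO cells at day 4 (-3.57).

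T, brachyury, was the next target. Its reads were 0.104 ± 0.254 against 0.126 ± 0.282 RPM in iPSCs (n = 6 and 5) and 8.47 ± 6.89 against 29.3 ± 24.7 RPM in iMeLCs. At day 2 they were 58.5 ± 51.3 against 121 ± 55.6 RPM, and at day 4, 31.2 ± 19 against 87.6 ± 33.6 RPM (log2 change -1.51, adjusted p = 0.908). T did not pass at any of the 4 stages. In BT-sorted cells at day 4 SOX17 was at 302 ± 81.3 against 358 ± 69.2 RPM and TFAP2C at 255 ± 70.5 against 317 ± 26.9 RPM. PRDM1 was at 131 ± 16.2 against 144 ± 37.6 RPM, and none of these 3 genes passed. The sort selects for PRDM1, so these values do not test germ cell induction. HOX genes at day 2 had 0 of 14 tested members called (3 lower adjusted over the list alone), with a median log2 change of -0.44. Camera gave adjusted p = 6.23e-07, and 0.117 with an estimated correlation. Replicates 1 and 4, of different clones and neighbouring library codes, stood apart at day 2. They had EOMES at 148 and 51.6 RPM, against at most 5.99 RPM in the other T KO libraries and 2.32 RPM in controls, and MIXL1 at 129 and 67.7 RPM, against at most 32.1 RPM in controls. At day 4 GZMK, a granzyme named after its values were seen, was the 1 gene that passed (0.87 ± 2.13 against 7.38 ± 5.03 RPM, log2 change -2.19, adjusted p = 0.0393, limma). Of 11 fits that left out a library 7 had 0. The count was 0 in iPSCs, iMeLCs and at day 2, with 429, 273 and 469 genes at an unadjusted p under 0.05 (limma). With sets of neighbouring library codes as a paired block 1 gene passed at day 2. Germ cell specification genes then had adjusted p = 0.000784 in iPSCs and 0.00558 at day 2, in the lower direction (0.338 and 0.488 with an estimated correlation). Fibroblast and smooth muscle genes had 0.0441 at day 2, also lower (0.537 with an estimated correlation). In simulated data of this design with 200 changed genes, 86.6% of those changed by a log2 of 1.5 were recovered. Recovery may be lower with few changed genes, and T (-1.51 at day 4) was not called.

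MIXL1, a homeobox gene of the primitive streak, gave 0.56 ± 0.491 against 2.42 ± 0.722 RPM in MIXL1 KO and control iPSCs (n = 4 and 4) and 688 ± 518 against 369 ± 233 RPM in iMeLCs. Its reads were 74.4 ± 71.1 against 31.2 ± 30.1 RPM at day 1, 30.6 ± 25.4 against 28.3 ± 18.4 RPM at day 2 and 34.2 ± 19.7 against 14.9 ± 4.95 RPM at day 4. None of these passed. DKK4 was the 1 gene lower in iMeLCs (4.12 ± 2.65 against 103 ± 102 RPM, log2 change -3.68 ± 0.49, adjusted p = 0.000108). SOX17 stood at 1.67 ± 1.74 against 16.3 ± 12.2 RPM there (adjusted p = 0.381), and passed without the 4 doubtful libraries (log2 change -2.65, adjusted p = 0.000203). At day 1 the endoderm list had 0 of 12 tested members called (4 lower adjusted over the list alone), with a median log2 change of -0.99. Its camera adjusted p was 8.61e-06, and 0.0102 with an estimated correlation. The apolipoprotein APOA1 was at 12.1 ± 19.5 against 169 ± 113 RPM. Without the 4 libraries the list had adjusted p = 0.104 with an estimated correlation. At day 4 SOX17 was at 422 ± 33 against 341 ± 201 RPM, TFAP2C at 451 ± 68.6 against 289 ± 168 RPM and PRDM1 at 197 ± 32.2 against 142 ± 96.3 RPM. Without the doubtful control the control means were 437 ± 75.5, 357 ± 119 and 182 ± 64.7 RPM, and SOX17 lay in the other direction. BTAG sorting selects for PRDM1 and TFAP2C, so these values do not test induction either. In iPSCs, at day 1, day 2 and day 4 the count was 0, with 161, 502, 547 and 590 genes at an unadjusted p under 0.05 (limma). It was 2 at day 2 without the 4 libraries and up to 7 at day 1 as single libraries were left out.

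Series 4 set EOMES KO cells with an added EOMES or SOX17 against controls. It holds no EOMES KO cells without an added gene, and BTAG sorting at days 2 and 4 selects for PRDM1 and TFAP2C. Restoration of germ cell transcripts was therefore not tested. EOMES reads were 74.7 ± 15.5 against 118 ± 49.3 RPM in +EOMES iMeLCs and 0 ± 0 against 2.22 ± 1.73 RPM at day 2. The deposited 3' reads did not show the added gene. SOX17 reads in +SOX17 cells were 0.0766 ± 0.153 against 2.85 ± 0.203 RPM in iMeLCs, 420.1 ± 16.3 against 536 ± 99.1 RPM at day 2 and 298 ± 31.2 against 365 ± 10.3 RPM at day 4 (n = 4 and 2). In +EOMES cells at day 2 SOX17 (488 ± 61.6 against 536 ± 99.1 RPM) and TFAP2C (383 ± 75.1 against 575 ± 122 RPM) did not pass. Nor did T (119.7 ± 19.9 against 175 ± 45.8 RPM) or PRDM1 (171 ± 26.8 against 260.5 ± 61.2 RPM). The extracellular matrix gene FBLN5 (26.6 ± 8.01 against 3.25 ± 3.2 RPM, log2 change 2.89) and TCL1B of the germ cell list (34.9 ± 8.38 against 6.12 ± 3.79 RPM, log2 change 2.41) rose. CD38, a surface protein of PGCLCs, rose too (27.6 ± 11.7 against 5.61 ± 3.75 RPM, log2 change 2.14). CDX2 (5.67 ± 2.51 against 36.8 ± 16.9 RPM, log2 change -2.51) and JUN (4.4 ± 1.32 against 23.9 ± 4.45 RPM, log2 change -2.22 ± 0.47, adjusted p = 0.00965) fell. Immediate early and heat shock genes had 2 of 14 tested members lower (2 lower adjusted over the list alone), with a median log2 change of -0.43. Camera gave adjusted p = 0.0246, and 0.234 with an estimated correlation. At day 4, 16 genes passed, among them TCL1A (40.3 ± 43.4 against 410.1 ± 133 RPM, log2 change -4.44 ± 0.85, adjusted p = 0.0278).

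In +SOX17 cells at day 2, T fell to 11 ± 7.51 against 175 ± 45.8 RPM, log2 change -4.07 ± 0.52, adjusted p = 3.63e-06. GAL (10.1 ± 5.94 against 206 ± 226 RPM, log2 change -3.72) and the streak factor EVX1 (4.87 ± 2.54 against 58.4 ± 5.8 RPM, log2 change -3.44) fell with it. CD38 (64.1 ± 29.7 against 5.61 ± 3.75 RPM, log2 change 3.32) and the keratin KRT7 (64 ± 51.7 against 4.6 ± 0.933 RPM, log2 change 3.19) rose. The interferon-induced GTPase MX1 rose as well (32.4 ± 25 against 2.74 ± 1.79 RPM, log2 change 2.80). TFAP2C (438 ± 253 against 575 ± 122 RPM) and PRDM1 (169 ± 53.6 against 260.5 ± 61.2 RPM) did not pass. The cell cycle list had 2 of 18 tested members lower (2 lower adjusted over the list alone), with a median log2 change of -0.57. Its camera adjusted p was 0.000204, and 0.327 with an estimated correlation. At day 4 TCL1A (6.73 ± 4.15 against 410.1 ± 133 RPM, log2 change -5.87 ± 0.85, adjusted p = 0.000117) was lower and T (31.4 ± 20.9 against 92 ± 18.9 RPM) did not pass. The interferon-induced ISG15 was higher (27.3 ± 14.7 against 2.03 ± 2.14 RPM, log2 change 3.22). IFI6 (38.1 ± 25 against 3.8 ± 4.64 RPM, log2 change 3.19) and IFI27 (64.3 ± 44.5 against 7.21 ± 5.79 RPM, log2 change 2.86) were higher as well. In +SOX17 iMeLCs GAL (111 ± 65.2 against 684 ± 303 RPM, log2 change -2.80) and CYP26A1 (9.29 ± 2.42 against 59.2 ± 10.5 RPM, log2 change -2.57) fell. In +EOMES iMeLCs the calcitonin receptor gene CALCR rose (29.8 ± 6.47 against 4.03 ± 3.99 RPM, log2 change 2.86). The endothelin receptor gene EDNRB was at 0 against 28 ± 1.37 RPM. FGF17 (16.3 ± 6.55 against 3.81 ± 3.69 RPM, log2 change 2.03) and GLIPR1 (15.5 ± 8.08 against 1.99 ± 1.12 RPM, log2 change 2.36), named after their values were seen, were higher.

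Against the controls, 87 genes were higher and 36 lower at day 2 in +EOMES cells and 439 and 330 in +SOX17 cells (limma). At day 4 they numbered 11 and 5, and 72 and 66. In iMeLCs 4 and 29 genes passed, and in iPSCs 0 in either, with 220 and 207 at an unadjusted p under 0.05 (limma). Single libraries moved these counts, from 1 to 28 (+EOMES) and 4 to 29 (+SOX17) in iMeLCs. With the code sets as a paired block they were 14 (+EOMES iMeLCs), 313 (+EOMES day 2) and 211 (+SOX17 day 4). For +EOMES at day 2 they were 6 and 367 without control replicate 1 and 2, and 35 and 37 without +EOMES replicate 2 and 4. For +SOX17 at day 2 they were 153 without control replicate 1 and 1495 and 470 without +SOX17 replicate 3 and 4. At day 4 they were 1 and 3 without control replicate 1, and 37 and 260 without control replicate 2. They were 2, 3, 51 and 3 without +EOMES replicate 1 to 4 and 71 without +SOX17 replicate 1. With the 2 groups alone in the fit the counts were 1 and 0 at day 2 (2303 and 1888 genes at an unadjusted p under 0.05, limma). At day 4 they were 0 and 0 (1112 and 1198 genes at an unadjusted p under 0.05, limma).

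Set against each other at day 2, +SOX17 cells had less LEFTY2 than +EOMES cells (79.6 ± 77.6 against 673 ± 279 RPM, log2 change -3.78 ± 0.56, adjusted p = 2.82e-05, n = 4 and 4). They had less T (11 ± 7.51 against 119.7 ± 19.9 RPM, log2 change -3.54), less EVX1 (4.87 ± 2.54 against 44.8 ± 6.86 RPM, log2 change -3.05) and less of the smooth muscle actin ACTG2 (28.5 ± 17.8 against 236 ± 56.7 RPM, log2 change -3.16). The FGF-binding protein FGFBP3 (23.2 ± 16.5 against 1.51 ± 1.67 RPM, log2 change 3.21) and the mitochondrial protein TSPO (43.8 ± 16.7 against 8.36 ± 3.13 RPM, log2 change 2.25) were higher. Cell cycle genes had 0 of 18 tested members called (0 adjusted over the list alone), with a median log2 change of -0.48. Their camera adjusted p was 1.49e-10, and 0.0202 with an estimated correlation. At day 4 the metallothioneins MT1H (103 ± 29.3 against 12.5 ± 4.72 RPM, log2 change 2.96) and MT1G (85.9 ± 16.8 against 13.5 ± 4.46 RPM, log2 change 2.61), which bind zinc and copper, were higher. MT1E (273 ± 32.8 against 48.4 ± 11.4 RPM, log2 change 2.49) and MT2A (192 ± 47 against 35.4 ± 7.76 RPM, log2 change 2.40) of the same family were higher too. EVX1 (1.98 ± 1.8 against 29.6 ± 17.6 RPM, log2 change -3.33) and WNT5B, a WNT ligand (6.13 ± 2.18 against 48.8 ± 23.9 RPM, log2 change -2.75), were lower in +SOX17 cells. In all 175 genes were higher and 140 lower at day 2, and 45 and 83 at day 4 (limma). With 1 value per clone they numbered 168 and 61, and with the 2 groups alone in the fit 117 and 18. At day 4 the count was 58 without +EOMES replicate 2 and 84 without +SOX17 replicate 2.

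BLIMP1 is a transcriptional repressor. In BLIMP1 KO iPSCs PRDM1 was the 1 gene that passed, and it was higher (6.61 ± 1.6 against 0.604 ± 0.181 RPM, log2 change 2.23 ± 0.32, adjusted p = 0.0168, n = 2 and 2). It was at 47.3 ± 13.4 against 98.7 ± 34.9 RPM at day 2, which did not pass. At day 4 it was at 31 ± 10.6 against 112 ± 9.62 RPM, log2 change -1.86 ± 0.32, adjusted p = 0.000345. SOX17 (259 ± 3.93 against 403 ± 10.4 RPM) and TFAP2C (199 ± 12.1 against 129 ± 37.2 RPM) did not pass at day 4. At day 2 the receptor phosphatase PTPRZ1 rose (109 ± 45 against 4.25 ± 1.19 RPM, log2 change 4.34 ± 0.35, adjusted p = 6.12e-07). The aminotransferase BCAT1 rose (log2 change 3.99), and EOMES was at 16.5 ± 13.5 RPM with both controls at 0. KRT7 fell (59.7 ± 29.3 against 561 ± 214 RPM, log2 change -3.25). Its list, amnion and surface ectoderm, had 2 of 13 tested members lower (8 lower adjusted over the list alone), with a median log2 change of -1.35. Camera placed amnion and surface ectoderm genes at adjusted p = 1.05e-05, and at adjusted p = 0.408 with an estimated correlation.

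At day 4 the BLIMP1 KO cells had more of the neural factor POU4F1 (155 ± 10.4 against 2.36 ± 1.58 RPM, log2 change 5.62 ± 0.50, adjusted p = 1.59e-07). Fibronectin FN1 (3021 ± 140.3 against 65.6 ± 11.3 RPM, log2 change 5.51) and ISL1 (76.5 ± 10.2 against 3.12 ± 4.41 RPM, log2 change 4.84) were higher too. Less was found of DLK1, a Notch ligand-like protein (0.189 ± 0.268 against 63.3 ± 9.57 RPM, log2 change -5.77). T (1.57 ± 0.614 against 65.8 ± 3.87 RPM, log2 change -4.72) and TCL1A (14.8 ± 18.2 against 225 ± 193 RPM, log2 change -4.30) were lower. The germ cell specification list had 8 of 15 tested members lower (8 lower adjusted over the list alone), with a median log2 change of -1.15. For germ cell specification genes camera gave adjusted p = 1.68e-06, and adjusted p = 0.242 with an estimated correlation. NANOS3 was at 11.4 ± 3.21 against 150.3 ± 0.365 RPM. Amnion and surface ectoderm genes moved in the direction opposite to day 2 and had 13 of 13 tested members higher (13 higher adjusted over the list alone), with a median log2 change of 3.13. For amnion and surface ectoderm genes camera gave adjusted p = 1.43e-10, and adjusted p = 0.241 with an estimated correlation. In all 160 genes were higher and 124 lower at day 2, and 1219 and 528 at day 4 (limma). The day 2 count was 3 with the 2 groups alone in the fit, 124 with no filter and 159 without control replicate 1. The PRDM1 call in iPSCs was lost with the 2 groups alone and with a pseudocount of 4. With 2 libraries against 2, the splits of a comparison are too few to weigh chance.

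TFAP2C KO and BLIMP1 KO cells shared genes at day 4, in 2 series with separate controls. Of 12048 genes tested in both, 246 were lower in both (54.2 for unrelated lists) and 598 higher in both (157 for unrelated lists), while 88 moved in opposite directions. T, NANOS3 and TCL1A were among the genes lower in both and ISL1, HAND1 and VTCN1 among those higher in both. Across genes, which are not independent replicates, the changes had a Pearson's r of 0.488. At day 2 it was 0.279, with 50 genes lower in both (5.12 for unrelated lists) and 44 higher in both (6.22).

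**Figure D3:**
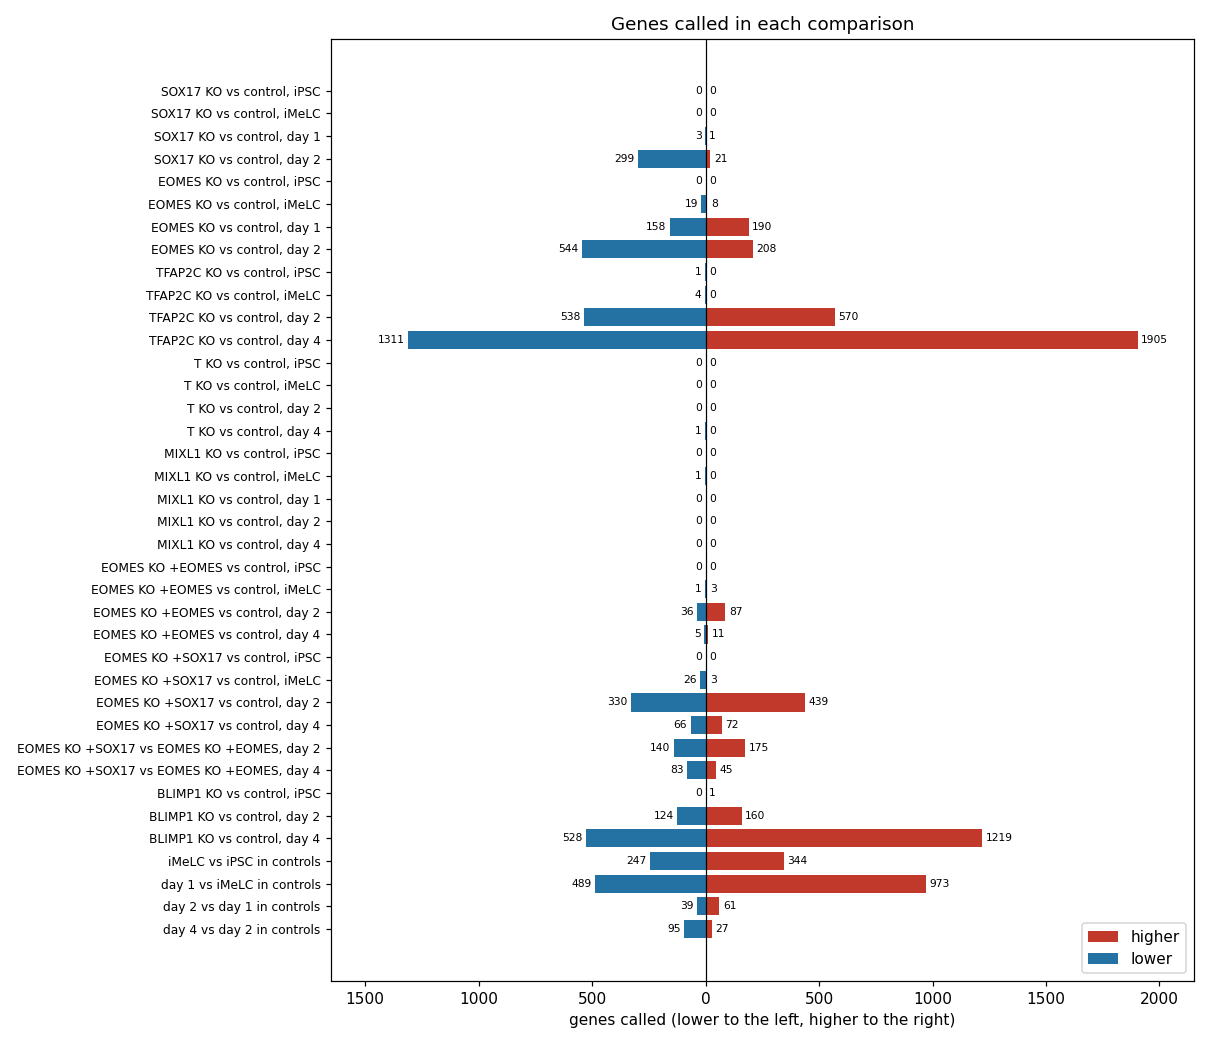
Number of genes called higher (bars above 0) and lower (bars below 0) in each of the 38 comparisons, by limma at an adjusted p under 0.05 and a log2 change of at least 1 in either direction. TFAP2C KO cells at day 4 had 1905 higher and 1311 lower, and the T KO and MIXL1 KO comparisons had at most 1.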

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

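The tests of depth for the 4 series 3 libraries and of 3 of them without the day 1 control, of the clones set apart, of the control that shares the EOMES KO prefix and of splits within sets were chosen after the result was seen, and the others were planned before it.

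In 84 tests (42 groups of 4 to 10 libraries on 2 lists), 8 values in 7 groups stood apart by Dixon's ratio, and for each list chance alone gives about 1 in 20 groups. For the mean of the germ cell specification list these were the series 2 control iPSC replicate 5 (0.834), the libraries labelled series 3 control day 1 replicate 4 (0.895), MIXL1 KO day 1 replicate 2 (0.840) and series 3 control day 4 replicate 2 (0.966), and EOMES KO +SOX17 day 4 replicate 3 (0.875). For the mean of the primitive streak list they were SOX17 KO day 2 replicate 4 (0.590), and the libraries labelled series 3 control day 2 replicate 1 (0.920) and series 3 control day 4 replicate 2 (0.886).

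The 4 libraries of series 3 resembled another stage more than their own, 4 of 224 checked, and have consecutive library codes. A low depth is argued against, since 7 of the 36 other libraries of the series had fewer reads than the shallowest of the 4. Over genes that mark the labelled stage, the library labelled control day 1 replicate 4 held 4.14% of that stage's level and the other 3 at most -0.100%. A negative share is below the background stage. Libraries of the stage they resemble reach at most 0.463%. A mixture with the labelled stage is thus argued against for those 3, which may carry the wrong label. For the day 1 control a mixture and a wrong label cannot be told apart, because its 4.14% is above the other libraries, while it held 84.2% of the day 4 level over genes of that stage. No biological explanation was tested, since the design has none within a group.

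The TFAP2C KO changes at day 4 were weighed next, as the cells were sorted on a reporter of PRDM1, which was low in them. A change private to 1 clone is argued against, because 98.7% of the 2809 genes called in clone 2 (3 libraries and 3 controls) moved the same way in clone 7 (2 and 2 other controls). Of the 2929 genes called in clone 7, 99.0% did so in clone 2. Cells of another type in the sort would lower germ cell genes to a like share. Over 32 such genes the share of the control level kept had an upper quartile 5.13 times the lower, between 1.37% and 7.04%. This does not decide, because the profile of the other cells was taken from day 2 aggregates, so a different composition of the sort could contribute beside the loss of TFAP2C, and the 2 cannot be told apart.

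The genes lower in both SOX17 KO and EOMES KO at day 2 (208) could come from the control libraries they share or from the library code prefix. With the controls divided between the comparisons 147 genes were lower in both, and with the prefixes kept apart 157, against 13.0 and 12.5 for unrelated lists. Shared controls or the prefix as the whole source are argued against. A single day 2 control carries the EOMES KO prefix. Over the 260 genes lower in SOX17 KO on the other prefixes it had a median log2 difference of 0.18 from the other controls (each of which lay between -0.85 and 0.89 from the rest), and the EOMES KO one of -1.88 from it. A common loss of SOX17, which EOMES KO aggregates also lacked, remains untested.

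The response of list members to a KO differed between stages by a test of the difference (limma). It differed for 24 members in SOX17 KO between day 2 and day 1, for 34 and 26 in EOMES KO between day 1 and iMeLCs and between day 2 and day 1, and for 46 and 94 in TFAP2C KO between day 2 and iMeLCs and between day 4 and day 2. In BLIMP1 KO it differed for 23 (day 2 and iPSCs) and 66 (day 4 and day 2), and in EOMES KO +SOX17 for 27 (day 2 and iMeLCs) and 10 (day 4 and day 2). Spike-in RNAs, which no comparison used, had a median of 30610 RPM in the 128 libraries that hold them.

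Splits of the libraries into other groups of the same sizes take libraries as independent, though clones, code sets and prefixes may tie them. A share of splits under 1 in 20 with as many genes thus does not exclude chance. For SOX17 KO at day 2 it was 3 of 100 (real 320, highest other 666). For EOMES KO it was 1 of 100 in iMeLCs (27, 15) and at day 1 (348, 242), and 3 at day 2 (752, 881). For TFAP2C KO it was 1 of 100 in iMeLCs (4, 1), at day 2 (1108, 486) and day 4 (3216, 1840). It was 1 of 35 for +SOX17 against +EOMES at day 2 (315, 99). In controls it was 1 of 35 for iMeLCs against iPSCs (591, 3) and day 1 against iMeLCs (1462, 6).

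Where the real count was 0, every split reaches it (100 of 100, or 35 of 35 for MIXL1 KO), so the splits decide nothing. Chance was not excluded for the others. For SOX17 KO at day 1 it was 10 of 100 splits (4, highest other 51), for TFAP2C KO in iPSCs 25 (1, 279), for T KO at day 4 22 (1, 48) and for MIXL1 KO in iMeLCs 3 of 35 (1, 9). It was 2 of 35 for +SOX17 against +EOMES at day 4 (128, 215), 3 for day 2 against day 1 in controls (100, 2108) and 6 for day 4 against day 2 (122, 1271). Splits with several times the real count point to a structure of the samples. The 2108 genes came from exchanging the libraries labelled control day 2 replicate 1 and control day 1 replicate 4. For SOX17 KO at day 2, control replicates 1 to 3 among 8 libraries gave the 666. With sets of neighbouring codes as a block and the control drawn within each set, SOX17 KO at day 2 had 1 of 81 splits (307, highest other 206) and at day 1 had 10 of 81 (2, 4). T KO at day 2 had 10 of 27 (1, 9), and in iPSCs, with a real count of 0, 27 of 27 (highest other 16). MIXL1 KO in iMeLCs makes 8 such splits, too few for a share under 0.05 (1, highest other 0).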

How the results depend on the processing

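Leaving out the 4 doubtful libraries of series 3 and the block of library code sets were chosen after the data were seen, and the other alternatives before. Of 555 alternative counts for the 38 comparisons, 385 were within 1.5 times the reported count and 170 were not, 87 of these among 320 that left out 1 library. Of 8242 alternative values for 590 gene results, 7111 kept their direction and side of the threshold, 1126 kept the direction and no longer passed, and 5 reversed. Low counts move by more than 1.5 times with few genes. A fit of the 2 groups alone has few residual degrees of freedom, and leaving out 1 of 2 libraries assumes that the other varies like the remaining groups. Library codes run in sets that join KO and control libraries for SOX17 KO, TFAP2C KO, T KO, MIXL1 KO and series 4. With these sets as a replicate block, counts were 2 (SOX17 KO day 1), 0 (TFAP2C KO iMeLC), 1, 1 and 2 (T KO iMeLC, day 2, day 4), 14 and 313 (+EOMES iMeLC, day 2) and 211 (+SOX17 day 4), and no other count moved. Of named genes 33 lost their call, all in TFAP2C KO, where only 2 sets hold a control, and described list calls that moved are given in the results. With 3 or 4 sets, r within sets was over 0.1 in every pair for SOX17 KO at day 1 and 2, T KO in iPSCs and at day 2 and MIXL1 KO in iMeLCs alone. No paired analysis was run for EOMES KO, BLIMP1 KO and the steps in controls, and the labels pair no libraries. For the KOs no such sets were clear or they held a single control. Control iPSC and iMeLC codes of series 3 do run in sets, but that step was not paired. Of the depths, the shallowest library had 595898 reads, so that genes of a few RPM rest on few reads. Scaling by the median ratio kept the counts within 1.5 times. MS102 libraries alone did too, but hold 1 control per stage. Except where the construction of an alternative is named here, the cause was not tested.

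The 5 reversed values came from the controls of series 1. They were FGF4 0.75 and COL3A1 -0.35 from iMeLCs to day 1, and RSPO3 0.73, TRIB1 0.83 and APOA1 0.94 from day 1 to day 2, as log2 changes. In those controls 1240 genes passed from iPSCs to iMeLCs and 1750 from day 1 to day 2. In the controls of series 2 the counts were 1262 from iPSCs to iMeLCs and 1140 from day 2 to day 4. Without the 4 doubtful libraries the steps gave 920 (iMeLC), 2303 (day 2) and 970 (day 4), and MIXL1 KO 2 in iMeLCs and 2 at day 2.

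With a fit of the 2 groups alone, counts were 0 (SOX17 KO day 1), 158 (SOX17 KO day 2), 1, 165 and 11 (EOMES KO iMeLC, day 1, day 2), 0 and 0 (TFAP2C KO iPSC, iMeLC), 0 (T KO day 4) and 0 and 1 (MIXL1 KO iMeLC, day 1). In series 4 this fit gave 1, 1, 1 and 0 (+EOMES iPSC, iMeLC, day 2, day 4), 2, 0 and 0 (+SOX17 iMeLC, day 2, day 4), 117 and 18 (+SOX17 against +EOMES day 2, day 4). It gave 0 and 3 (BLIMP1 KO iPSC, day 2) and 893, 0 and 0 (controls iMeLC, day 2, day 4). In the reported limma fit the SOX17 KO day 2 comparison had 1868 genes at an unadjusted p under 0.05.

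With 1 value per clone, counts were 0 and 172 (SOX17 KO day 1, day 2), 0 (TFAP2C KO iMeLC), 0 (T KO day 4), 8, 356 and 27 (+EOMES iMeLC, day 2, day 4) and 168 and 61 (+SOX17 against +EOMES day 2, day 4), where fewer values enter. With no filter they were 8 (SOX17 KO day 1), 1 and 17 (EOMES KO iPSC, iMeLC), 4 and 1 (TFAP2C KO iPSC, iMeLC), 1 and 5 (T KO iPSC, day 4) and 1, 3, 8, 2 and 1 (MIXL1 KO iPSC, iMeLC, day 1, day 2, day 4). Also with no filter they were 2 and 12 (+EOMES iPSC, iMeLC), 3 (+SOX17 iPSC) and 4 and 124 (BLIMP1 KO iPSC, day 2). With a pseudocount of 4 they were 2 and 175 (SOX17 KO day 1, day 2), 0 and 656 (TFAP2C KO iPSC, day 2), 2 (T KO day 4), 3 (MIXL1 KO day 1), 33 and 8 (+EOMES iMeLC, day 4) and 0 (BLIMP1 KO iPSC), since a larger pseudocount shrinks low genes. Without the prefix term the counts were 7 (SOX17 KO day 1) and 1, 56 and 187 (EOMES KO iPSC, iMeLC, day 1). With it they were 0 and 2 (TFAP2C KO iPSC, iMeLC) and 0 (T KO day 4). Of 760 gene list tests 140 passed, 34 with an estimated correlation and 133 when scaled, 127 of them in common and none in another direction.

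Leaving out single libraries gave these lowest and highest counts: SOX17 KO 1 and 10 (day 1); EOMES KO 13 and 24 (iMeLC), 103 and 420 (day 1), 262 and 989 (day 2); TFAP2C KO 0 and 11 (iPSC), 0 and 4 (iMeLC); T KO 0 and 2 (day 2), 0 and 4 (day 4); MIXL1 KO 0 and 1 (iPSC), 0 and 7 (day 1), 0 and 1 (day 2), 0 and 3 (day 4). For +EOMES they were 0 and 2 (iPSC), 1 and 28 (iMeLC), 6 and 367 (day 2) and 1 and 51 (day 4). For +SOX17 they were 0 and 1 (iPSC), 4 and 29 (iMeLC), 153 and 1495 (day 2) and 3 and 260 (day 4), and for +SOX17 against +EOMES 58 and 169 (day 4). For BLIMP1 KO they were 2 and 5 (iPSC) and 159 and 283 (day 2), and for controls 20 and 1010 (day 2) and 30 and 630 (day 4). In the other comparisons no count moved by over 1.5 times. SOX17 KO at day 2 lay between 222 and 467, TFAP2C KO between 887 and 1146 (day 2) and 3131 and 3261 (day 4), BLIMP1 KO at day 4 between 1292 and 1450 and controls between 397 and 544 (iMeLC) and 1217 and 1534 (day 1).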

Other observations

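The shared direction of the TFAP2C KO and BLIMP1 KO changes was tested as a hypothesis fixed beforehand, and the genes and values in the other paragraphs were chosen after the data were seen.

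Endothelial genes appeared in 2 of the 5 TFAP2C KO libraries at day 4, 1 of each clone. The VEGF receptor gene KDR was at 446 RPM in replicate 1 (clone 2) and 356 RPM in replicate 4 (clone 7), against 19.6, 34.9 and 49 RPM in replicates 2, 3 and 5 and 9.27 ± 2.75 RPM in controls (SD, n = 5). The adhesion gene ESAM was at 293 and 319 RPM in the former and at 9.8, 4.28 and 12.2 RPM in the latter, and the cadherin CDH5 at 146 and 137 RPM and at 1.23, 0 and 8.16 RPM. SOX17 is also an endothelial factor. As a list, the endothelial genes had 4 of 5 tested members higher (4 higher adjusted over the list alone), with a median log2 change of 2.68. Camera gave adjusted p = 0.0136, and 0.253 with an estimated correlation.

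TCL1A separated the clones of the EOMES KO +EOMES cells. In controls of series 4 it went from 22.1 ± 15.2 RPM at day 2 to 410.1 ± 133 RPM at day 4 (SD, n = 2). EOMES KO +EOMES cells at day 4 had 87.3 and 67.2 RPM in clone 5 and 2.73 and 4.17 RPM in clone 14, whereas in +SOX17 cells the clones overlapped (12.2 and 5.65 RPM, and 2.16 and 6.93 RPM). The interferon-induced ISG15 was also higher outside series 4, at 62 ± 45.4 RPM in TFAP2C KO and 3.49 ± 2.19 RPM in control cells at day 4 (n = 5 each).

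The single libraries of series 5 follow control PGCLCs to day 8. SOX17 went from 0.915 RPM in iMeLCs to 304 at day 2 and 409 at day 8, and NANOS3 from 0 to 149.6 and 394. TCL1A reached 328, 706 and 644 RPM at days 4, 6 and 8. The de novo methyltransferase DNMT3B went from 736 in iMeLCs to 45.3 at day 2 and 14.4 at day 8, and SOX2 from 152 to 0.453 RPM at day 2. DDX4 and MAEL, late germ cell genes, were at 0 in all 6 libraries, and DAZL at 4.76 RPM in iPSCs and 0 from day 4, while DPPA3 was at 0 up to day 2 and at 0.512, 2.86 and 4.60 RPM at days 4, 6 and 8.

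Of lists not described so far, 5 results passed with both correlations. From iPSCs to iMeLCs in controls, naive pluripotency genes had 2 of 5 tested members higher (2 higher adjusted over the list alone), with a median log2 change of 0.30. Camera gave adjusted p = 0.0305, and 0.0415 with an estimated correlation. Endoderm genes were higher at that step (adjusted p = 0.000338, and 0.0201 with an estimated correlation), and core pluripotency genes lower from iMeLCs to day 1 (0.000129 and 0.0238). Endoderm genes were lower in +SOX17 iPSCs (0.00161 and 0.0172) and iMeLCs (0.0119 and 0.0324).

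A shared direction of the TFAP2C KO and BLIMP1 KO changes at day 4 was tested over the genes tested in both series. Pearson's r was 0.488, and more than the chance number of genes moved together. TFAP2C KO cells also had little PRDM1 (12.1 against 144 RPM), so dependence on both factors cannot be told from loss of BLIMP1 alone. The gates differed (BT and BTAG), and whether a common outcome of the sort gives this was not tested.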
